A study of Canis lupus familiaris with 12 samples.

How the data were processed

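Transcripts were measured by bulk RNA sequencing in MDCK cells, a line of dog kidney epithelial cells, grown with or without 25 µM Yoda1, a small molecule that opens the mechanosensitive ion channel Piezo1. The labels give 12 libraries in 4 groups of 3: C1 and C2 without Yoda1, T1 after 12 h and T2 after 24 h with it. The deposited sample sheet gives C1 as the 12 h control and C2 as the 24 h control. The vehicle of the controls is not given in the sources used here. The labels number the replicates 1 to 3 and do not say that they came from separate cultures, so p-values measure the spread between these libraries, which may be technical. All 12 libraries carry lane 5 in the sample sheet, so lanes cannot separate the groups.

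Per the labels' protocols, polyadenylated RNA was made into strand-specific libraries and read as 101 bp pairs. Per the submitters' processing notes, fastp 0.23.4, STAR 2.7.10b and RSEM 1.3.3 are named; the genome build and annotation are not given in the sources used here. The expected counts per gene were made by the authors before deposit, estimated from the reads with RSEM among the named tools per the submitters' processing notes, and were not normalized; 91.1% of the values, zeros included, equal their rounded value exactly. The authors deposited TPM for the same genes, in which each library is scaled to the same total. The deposited sample sheet holds condition, time and lane for each library (unit: other, no measured values). The tables hold 31121 gene IDs, of which 13022 are paired with a symbol. The 18099 IDs without a symbol held 33.1% to 34.1% of the counts per library and are not named. Those among them that passed the filter on low counts entered the gene tests. No ID is paired with the symbol PIEZO1, so that gene could not be followed by name. The gene table given with the data describes another assembly and matched none of the IDs, so no coordinates are printed. RSEM can divide reads between near-identical copies, so genes of multigene families and the 2 IDs that share the symbol OASL are uncertain.

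Expected counts were rounded to whole numbers. Genes were kept by the filterByExpr function of edgeR 4.0.16 (R 4.3.3), which left 14169 genes, 7682 of them with a symbol. Counts were scaled by TMM and 1 robust quasi-likelihood model with a mean per group was fitted to all 12 libraries. It tested T1 against C1, T2 against C2, the difference between these responses, and C2 against C1. P-values were adjusted by Benjamini-Hochberg and a gene was called at an adjusted p under 0.05. Standard errors are the absolute log2 fold change divided by the root of the F statistic. Levels are CPM, counts scaled to the TMM-adjusted library size, as mean ± SD of 3 libraries. Library totals ran from 20709218 to 38889592 counts and the common biological coefficient of variation was 13.3%. On simulated counts for T1 against C1 over the 14169 genes, the test recovered 51% of the 1.5-fold and 77% of the 2-fold changes among 200 changed genes, with 4 false calls. On the same counts DESeq2 gave 146 true and 28 false calls, and limma voom 122 and 4. The larger counts of DESeq2 below should be read with this in mind.

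Before the data were examined, 35 gene lists with 1147 distinct symbols were fixed; the files name 711 of the symbols, and 31 lists had at least 5 tested members. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, and again with an estimated correlation and with fry. The genes named in the text follow a rule fixed at the same time. They are PIEZO1 and CDH1. They are also the 8 highest and 8 lowest log2 fold changes among called genes at each time with a symbol, a mean of at least 5 CPM and no overlap of treated and control libraries. Up to 4 called members per list with the largest change were added, with 5 and 5 genes for the difference between times and 3 and 3 for C2 against C1. Of these, the text gives values at 12 h and 24 h mainly for genes that kept their call in each fit that left out a library, a choice made after the values were seen. Others were left out for length, and some results are not reported here. A gene outside the rule is named as chosen after its values were seen. The genes of the clock list in the closing observations stand outside the rule.

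The replicate numbers were checked as pairs through the correlation of deviations from the group means. Between C1 and T1 the correlations were 0.153, 0.283 and 0.115 for replicates 1, 2 and 3, all over 0.1 and each highest with its own number. The numbers were therefore taken to pair the samples at 12 h, from the data and not from the labels. This pairing is an assumption, since the correlations are low and 3 numbers can match by chance. Between T1 and T2, not taken as paired, replicates 1 and 2 correlated at 0.23 and 0.172, each highest with its own number. Replicate 3 correlated there at -0.0805. At 24 h the numbers were not taken to pair the samples. Alternatives were DESeq2 1.42.0, limma voom, RLE size factors, library size only, other filters, the replicate block, 6 libraries per fit, pooled controls, a minimum fold, log2(TPM + 1) with limma for genes with a mean of at least 1 TPM, and leaving out each library in turn. A correction for gene length, camera on log2 CPM with and without it, and a replicate block in the 6 libraries of the 12 h comparison were added after the data had been seen. Within groups, the Pearson correlation of log2 CPM was 0.9746 to 0.9894 and the chi-square per gene 5.23 to 89.9, so no pair of libraries was as close as sampling noise and each was counted once.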

Results

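Gene expression was measured in MDCK dog kidney epithelial cells exposed to 25 µM Yoda1, an agonist of the ion channel Piezo1, for 12 h (T1) or 24 h (T2), with a control group for each time (C1 at 12 h, C2 at 24 h) and 3 libraries per group. The series is about Piezo1 activation, the closing of gaps in an epithelium and the genes of cell adhesion. Library totals were 20709218 to 37241313 counts in C1, 25822695 to 30999725 in T1, 33150371 to 38889592 in C2 and 27915926 to 36545726 in T2. The first principal component, with 23.3% of the variance, separated all treated from all control libraries. The C2 libraries differed most among themselves, with a chi-square per gene of 89.9 between replicates 1 and 2.

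The first comparison asked which transcripts differed after 12 h with Yoda1. CDH1 (ENSCAFG00845010704), which encodes E-cadherin, the main adhesion receptor of epithelial adherens junctions, fell from 1080 ± 99 CPM in C1 to 733 ± 47.2 CPM in T1 (log2 fold change -0.56 ± 0.09 SE, edgeR adjusted p = 0.0044, n = 3 per group). CLDN1 (ENSCAFG00845024289), a tight junction strand protein, fell from 480 ± 28.3 to 278 ± 13 CPM (-0.79 ± 0.08, edgeR adjusted p = 0.00042). COL17A1 (ENSCAFG00845028642), a hemidesmosome collagen, fell 2.1-fold from 1220 ± 84.4 to 578 ± 39.6 CPM. ITGB1 (ENSCAFG00845002947), the integrin beta-1 subunit, fell from 834 ± 76.3 to 572 ± 43.3 CPM. MALL (ENSCAFG00845007406), a membrane raft protein, fell 4.5-fold, from 150 ± 6.35 to 33.3 ± 2.13 CPM (edgeR adjusted p = 2.1e-06).

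In all, 990 of 14169 genes were called at 12 h by edgeR's quasi-likelihood test, 427 higher and 563 lower, and 145 of them changed at least 2-fold (16 higher, 129 lower). Genes that rose included KIF5C, a neuronal kinesin (1.32 ± 0.18), FHDC1, a formin (1.16 ± 0.14), GNMT, a glycine methyltransferase (0.89 ± 0.17), and the stress-induced transcription factor ATF3 (0.89 ± 0.10). Genes that fell included NCCRP1 (-1.80 ± 0.28), the WNT ligand WNT5A (-1.53 ± 0.21), ARHGDIB (-1.45 ± 0.18), GDPD2 (-1.44 ± 0.17) and PPP1R3C, a regulator of glycogen synthesis (-1.34 ± 0.19). The count depended on single libraries: it was 402, 467 and 358 without C1 replicates 1, 2 and 3, 265 and 185 without T1 replicates 1 and 3, and 1693 and 1695 without C2 replicates 1 and 2. The genes given with values for 12 h were chosen because they kept their call in all 12 fits that left out a library, as 27 of the 67 genes of the naming rule did; the other 40 lost it in at least 1. Of the highest and lowest genes of that rule, MMP9 (-2.06 ± 0.48), UPK3A (-1.54 ± 0.38), CEMIP (1.5 ± 0.36), PDE3A (1.09 ± 0.21) and KAT14 (0.88 ± 0.22) lost it in 7, 5, 7, 2 and 5 fits, all 5 of them without C1 replicate 3 and without T1 replicate 1. With the replicate block in the 6 libraries of the 12 h comparison, where the numbers were assumed to pair the samples, 4339 genes were called. That fit had only 2 residual degrees of freedom. Scaled by library size only, 59.4% of 1255 called genes were higher against 43.1% in the main count, and 67.9% of 1049 with log2(TPM + 1).

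By gene group, 4 of 17 adherens junction genes fell at 12 h and none rose (2 rose and 5 fell when adjusted over the list alone). Beside CDH1 these included NECTIN4 (-0.89 ± 0.14), an adherens junction nectin. In the tight junction list 5 of 20 fell and 1 rose (adjusted over the list alone, 5 and 1), among them CLDN16 (-2.33 ± 0.30), a renal claudin at only 3.47 CPM in C1, and the scaffold TJP3 (-0.75 ± 0.14). Of 9 desmosome and hemidesmosome genes 1 fell, COL17A1 (adjusted over the list alone, 2 fell). Of 22 integrin and focal adhesion genes 5 fell and 1 rose (adjusted over the list alone, 8 and 1). The camera test put the 4 lists lower than other genes, with adjusted p of 0.0172, 0.0165, 0.0173 and 0.000199 in the order given. With an estimated correlation no call held (adjusted p = 0.432, 0.385, 0.385 and 0.385 with an estimated correlation). Without C1 replicate 3 the adherens, tight junction and desmosome lists were no longer called (adjusted p = 0.106, 0.0717 and 0.0881), nor was the tight junction list without T1 replicate 2 (adjusted p = 0.0561). By camera on log2 CPM the tight junction and desmosome lists were not called either (adjusted p = 0.0617 and 0.0642), and other splits of the 6 libraries called up to 11 lists where the real one called 16.

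**Figure D1:**
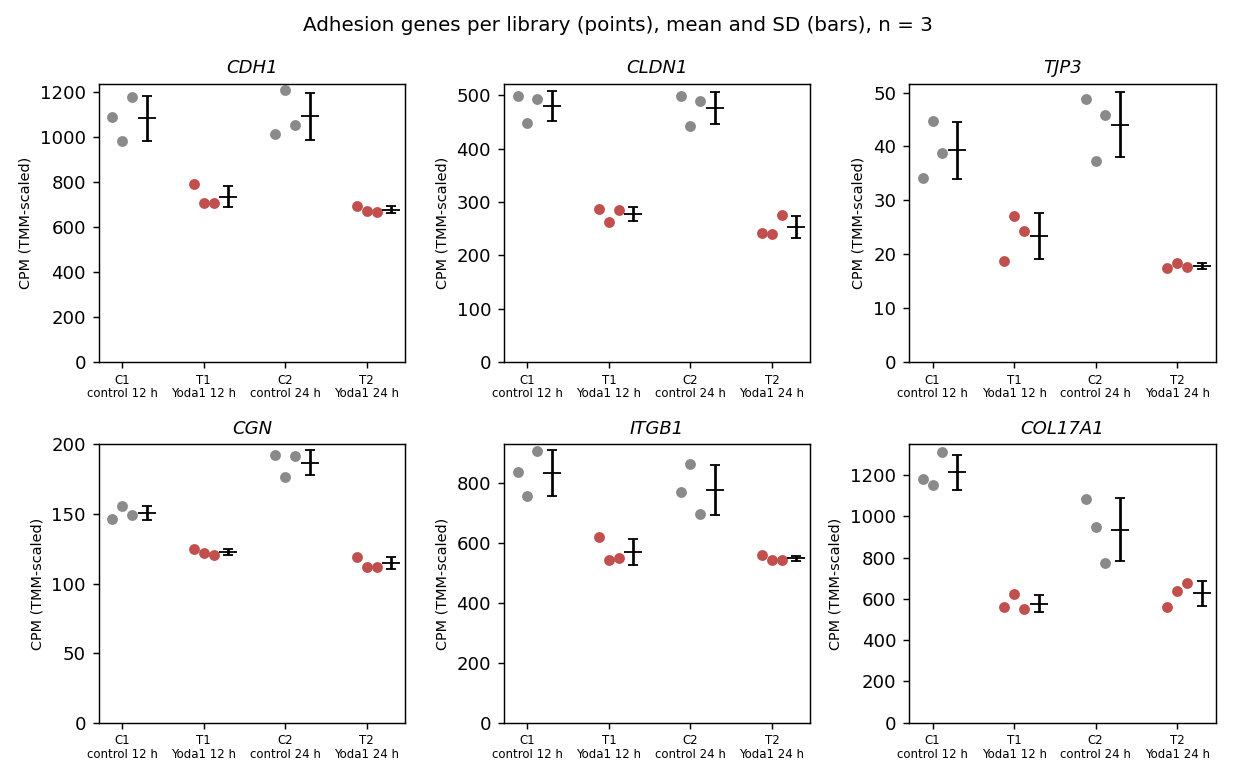
Levels of 6 adhesion genes in TMM-scaled CPM (vertical axes, from 0) in each library of C1, T1, C2 and T2; points are libraries, and bars to their right give mean and SD of 3. CDH1 averaged 1080 CPM in C1 and 733 CPM in T1, and 1090 CPM in C2 and 675 CPM in T2.

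Of 11 extracellular matrix genes 3 fell at 12 h (adjusted over the list alone, 6 fell; camera adjusted p = 6.6e-05). In the list of matrix proteases and inhibitors 3 of 19 fell (adjusted over the list alone, 1 rose and 6 fell; camera adjusted p = 0.000164), including TIMP1, an inhibitor of metalloproteinases (-0.97 ± 0.16). With an estimated correlation these gave adjusted p = 0.385 and 0.115. Of 31 calcium channel, pump and sensor genes 7 fell (adjusted over the list alone, 10 fell; camera adjusted p = 0.000199, adjusted p = 0.168 with an estimated correlation), among them ANXA1, a calcium-dependent membrane-binding protein (-0.72 ± 0.12). The unfolded protein response list held 3 genes that rose and 7 that fell of 29 (adjusted over the list alone, 5 and 11; camera adjusted p = 0.0173, adjusted p = 0.168 with an estimated correlation). HSP90B1, an endoplasmic reticulum chaperone, fell from 1100 ± 67.6 to 549 ± 21.1 CPM, and PDIA3 fell by 0.67 on the log2 scale. With the replicate block in 6 libraries the unfolded protein response list was no longer called (adjusted p = 0.0955), and it was not called without T1 replicate 3 (adjusted p = 0.0751) or by camera on log2 CPM (adjusted p = 0.074). Of 13 WNT and Notch genes 3 fell (adjusted over the list alone, 5 fell; camera adjusted p = 0.000274, adjusted p = 0.168 with an estimated correlation), with WNT7B at -0.70 ± 0.09.

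The lists past the threshold in the higher direction at 12 h were those of the cell cycle. In the S phase list 3 of 26 genes rose and none fell (adjusted over the list alone, 9 rose; camera adjusted p = 6.6e-05, adjusted p = 0.462 with an estimated correlation), with CDC6, a licensing factor of DNA replication, at 0.69 ± 0.12. In the G2/M list 1 of 30 rose (adjusted over the list alone, 6 rose; camera adjusted p = 2e-05, adjusted p = 0.385 with an estimated correlation). The median log2 fold changes were 0.254 for S phase and 0.195 for G2/M at 12 h, and 0.189 and 0.222 for C2 against C1. Both comparisons use the C1 libraries, so low values in C1 alone would raise both. At 24 h, in a comparison without the C1 libraries, the medians were 0.168 for S phase and 0.1 for G2/M. There 4 of 26 and 5 of 30 genes rose and 0 fell, and camera called neither list (adjusted p = 0.0891 and 0.127). The actomyosin list (3 of 27 fell; adjusted over the list alone, 4), the epithelial-mesenchymal transition list (3 of 18 fell; adjusted over the list alone, 1 rose and 5 fell) and the epithelial and renal tubule identity list (of 24, 0 called by edgeR, 11 at an unadjusted p under 0.05, 7 by DESeq2 and 0 by limma voom; adjusted over the list alone, 9 fell) were lower by camera. Their adjusted p were 0.00552, 0.00102 and 0.00656, and with an estimated correlation adjusted p = 0.463, 0.385 and 0.424. The oxidative phosphorylation and ribosomal protein lists were lower with camera adjusted p of 0.0173 and 0.0249, and adjusted p = 0.705 and 0.896 with an estimated correlation. Of their 30 and 82 genes edgeR called 0 and 0, also adjusted over the list alone, with 2 and 0 at an unadjusted p under 0.05, 1 and 0 called by DESeq2, and 0 and 0 by limma voom. By camera on log2 CPM their adjusted p were 0.00657 and 0.0127, and with length correction in that test neither list was called (adjusted p = 0.0532 and 0.638). Without C1 replicate 2 the adjusted p by camera on counts were 0.29 and 0.659, and the ribosomal list's median log2 fold change turned from -0.097 to 0.008. Without T1 replicate 1 neither was called (adjusted p = 0.0988 and 0.281), nor was the ribosomal list without C2 replicate 1 or T1 replicate 3 (adjusted p = 0.0574 and 0.133). The other lists did not pass the test at 12 h. Among them the immediate early list held 4 genes that rose, ATF3 among them, and 3 that fell of 20 (adjusted over the list alone, 5 and 4), with EGR1, a serum-response transcription factor, at -1.02 ± 0.14. In the NRF2 list 2 of 22 rose (adjusted over the list alone, 2), with TXNRD1, a thioredoxin reductase, at 0.84 ± 0.13. Median, mean and test differed in sign in the p53 list (median -0.035, mean -0.016, test upward), the NF-kB list (0.019, -0.238, downward), the interferon-stimulated list (0.066, -0.025, upward) and the replication-dependent histone list (-0.013, 0.076, upward).

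**Figure D2:**
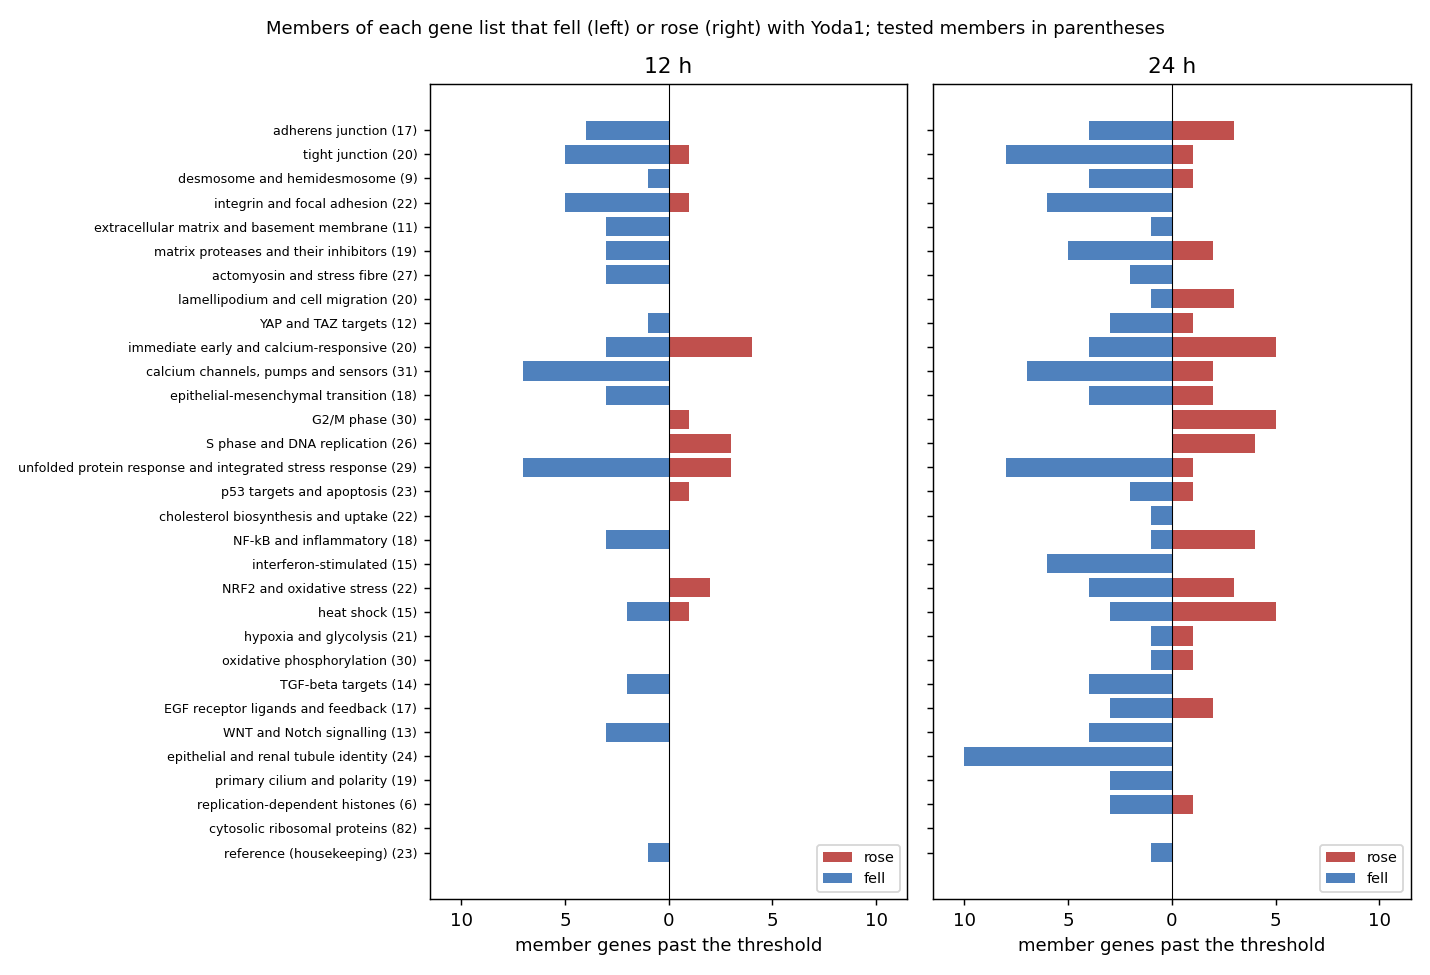
Number of genes of each list called lower (blue, to the left) and higher (red, to the right) at 12 h and 24 h; the number of tested members stands in parentheses after each list. At 24 h, 10 of 24 epithelial and renal tubule identity genes and 8 of 20 tight junction genes fell.

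After 24 h with Yoda1 several adhesion genes were lower, while other members of the adherens junction list rose. CDH1 fell from 1090 ± 104 CPM in C2 to 675 ± 15.4 CPM in T2 (-0.69 ± 0.09, edgeR adjusted p = 0.00057, n = 3 per group), CLDN1 from 477 ± 29.8 to 253 ± 20.2 CPM, and the tight junction scaffolds TJP3 (ENSCAFG00845008169) from 44 ± 5.98 to 17.8 ± 0.556 CPM and CGN (ENSCAFG00845023683) from 187 ± 9.04 to 114 ± 4.22 CPM. ITGB1 fell from 777 ± 83.9 to 549 ± 8.65 CPM and COL17A1 from 936 ± 154 to 626 ± 59.6 CPM. AREG (ENSCAFG00845006713), which encodes amphiregulin, a ligand of the EGF receptor, rose from 6.99 ± 4.94 to 74.6 ± 7.7 CPM (3.41 ± 0.38, edgeR adjusted p = 0.00057). Its size depended on C2 replicate 1, at 12.69 CPM against 4.316 and 3.953 in the other C2 libraries, without which the log2 fold change was 4.17.

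In all, 2630 genes were called at 24 h, 1269 higher and 1361 lower, and 373 changed at least 2-fold (100 higher, 273 lower). Genes that rose included KIF5C (1.55 ± 0.18), PTGS2, the inducible cyclooxygenase (1.55 ± 0.29), FHDC1 (1.26 ± 0.14), SLC6A17 (1.24 ± 0.17) and IFRD1 (1.22 ± 0.16). Genes that fell included ANXA13 (-2.12 ± 0.44, and -1.35 without C2 replicate 1), IFGGC1 (-1.96 ± 0.34), the small heat shock protein HSPB8 (-1.82 ± 0.20), TNFSF10, the death ligand TRAIL (-1.73 ± 0.22), TRPM3 (-1.70 ± 0.24) and DEPTOR, an inhibitor of mTOR (-1.69 ± 0.31). The count was 1640 without C2 replicate 3, 1269 without T2 replicate 2 and 1138 without T2 replicate 3. When only the 6 libraries of the 2 groups were fitted, 1080 genes were called at 24 h against 1673 at 12 h. The order of the 2 times was then the reverse of that in the main fit. A response that grows with time can thus not be read from the counts. The genes given with values for 24 h were likewise chosen among the 69 of 111 that kept their call in all 12 fits that left out a library, while 42 lost it in at least 1. Of the highest and lowest genes, MMP9 (-2.25 ± 0.48) and CEMIP (1.55 ± 0.36) lost it without T2 replicate 2 (edgeR adjusted p = 0.056 and 0.058), and SULF1 (1.47 ± 0.45) in 11 fits, all but that without C2 replicate 1. With log2(TPM + 1), 61.4% of the called genes were higher against 48.3% in the main count.

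By gene group at 24 h, 8 of 20 tight junction genes fell and 1 rose (adjusted over the list alone, 8 and 1; camera adjusted p = 0.000202, adjusted p = 0.311 with an estimated correlation). In the epithelial and renal tubule identity list 10 of 24 fell and none rose (adjusted over the list alone, 11 fell; camera adjusted p = 6.04e-05, adjusted p = 0.347 with an estimated correlation). They included the transcription factors TFAP2A (-1.18 ± 0.17) and OVOL1 (-0.87 ± 0.14) and the sodium pump subunit ATP1B1 (-0.84 ± 0.14). Of 15 interferon-stimulated genes 6 fell (adjusted over the list alone, 10 fell; camera adjusted p = 3.95e-07, adjusted p = 0.311 with an estimated correlation). OAS3, an antiviral oligoadenylate synthetase, fell from 175 ± 40 to 73.3 ± 5.37 CPM, and OAS1 and USP18 fell by 1.37 and 0.92 on the log2 scale. In the unfolded protein response list 8 of 29 fell and 1 rose (adjusted over the list alone, 10 and 1; camera adjusted p = 0.00266, adjusted p = 0.114 with an estimated correlation), with SESN2 at -0.88 ± 0.10 and HERPUD1 at -0.80 ± 0.10.

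The remaining lists did not pass camera at 24 h. In the adherens junction list 3 genes rose and 4 fell of 17 (adjusted over the list alone, 3 and 7). Of 22 integrin and focal adhesion genes 6 fell (adjusted over the list alone, 1 rose and 7 fell), among them the kinase SRC (-0.50 ± 0.06) and PARVA (-0.46 ± 0.07). Of 9 desmosome and hemidesmosome genes 4 fell and 1 rose (adjusted over the list alone, 5 and 1). In the heat shock list 5 of 15 rose and 3 fell (adjusted over the list alone, 5 and 3), with CRYAB at 0.61 ± 0.12, HSPA8 at 0.48 ± 0.09 and HSPB1 at -0.86 ± 0.13. TXNRD1 of the NRF2 list rose from 292 ± 54.9 to 659 ± 19.2 CPM, while catalase (CAT) fell (-0.54 ± 0.06), among 3 that rose and 4 that fell of 22 (adjusted over the list alone, 3 and 4). VEGFA fell (-1.07 ± 0.14) and NDRG1 rose (0.73 ± 0.12), the called genes of 21 in the hypoxia list (adjusted over the list alone, 1 and 1). The immediate early list held 5 genes that rose and 4 that fell of 20 (adjusted over the list alone, 6 and 4), with EGR1 at -1.16 ± 0.14 and FOSL2 at 0.75 ± 0.13. Without C1 replicate 3, C2 replicate 3 or T2 replicate 3 the number of lists called at 24 h was 7, 16 and 7 against 4, and with pooled controls it was 18. Of the 10 splits of the 6 libraries the real one called the fewest lists, 4, and the others called 6 to 16. The number of lists called at 24 h thus gave no support beyond an arbitrary division of these libraries. Median, mean and test differed in sign in the heat shock list (median 0.081, mean -0.037, test upward) and the cholesterol list (0.009, -0.036, downward).

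The responses at both times were compared gene by gene. There were 284 genes that rose and 345 that fell at both times, where 38.2 and 54.1 would be called in both if the lists of calls were independent, and 5 genes changed in opposite directions. The 1 of these with a symbol was MOB3B (0.38 at 12 h and -0.24 at 24 h), named after its values were seen. The T1 and T2 comparisons use separate controls. Of the 990 genes called at 12 h, 926 (93.5%) had the same direction at 24 h. Across all genes, which are not independent replicates, Pearson's r of the log2 fold changes was 0.301 and Spearman's rho 0.53. The 629 shared calls became 275, 291 and 249 without C1 replicates 1, 2 and 3, 191 and 130 without T1 replicates 1 and 3, 362 and 338 without T2 replicates 2 and 3, and 1043 without C2 replicate 2.

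**Figure D3:**
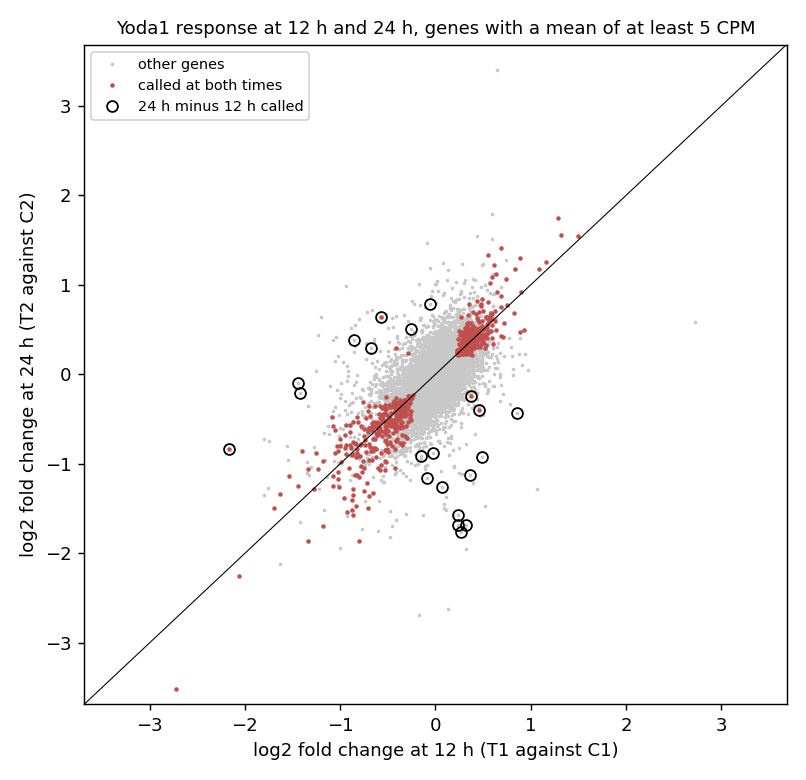
Log2 fold change at 12 h (horizontal axis) against that at 24 h (vertical axis) for 10415 genes with a mean of at least 5 CPM; red points are 564 genes called at both times, and black circles are 21 genes whose response differed between times. The line marks equal change. The slope over all genes called at both times, fitted through the origin, was 0.977. That selection favours genes with similar changes, and Pearson's r across all 14169 tested genes was 0.301.

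The difference of the responses was called for 22 genes, 9 with a higher and 13 with a lower log2 fold change at 24 h than at 12 h. MALL was lower by 2.17 on the log2 scale at 12 h and its difference was 1.34 ± 0.16 (edgeR adjusted p = 0.013, n = 3 per group). GDPD2 (1.34 ± 0.23), TMEFF2 (0.97 ± 0.15), PINX1 (0.85 ± 0.13) and the phospholipase PLA2G4A (0.77 ± 0.12) went in the same direction. Part of these differences lay in the controls, since for each of these genes every C2 library was below every C1 library. TMEFF2 was 169.5 to 198.7 CPM in C1 and 95.25 to 120.3 CPM in C2. In T1 it was 102.5 to 127.9 CPM and in T2 128.5 to 140.7 CPM. TEF (ENSCAFG00845017239), a transcription factor with circadian expression, averaged 9.67 ± 1.12 CPM in C1, 11.4 ± 0.732 in T1, 18.8 ± 4.33 in C2 and 6.32 ± 0.837 in T2, a difference of -1.81 ± 0.24. The interferon-responsive genes RTP4 (-2.00 ± 0.30), DHX58 (-1.92 ± 0.28), PARP9 (-1.48 ± 0.22) and USP18 (-1.41 ± 0.21) had a lower response at 24 h than at 12 h. Part of this also lay in the controls. RTP4 was 5.707 to 7.77 CPM in C1 and 8.825 to 14.98 in C2, and USP18 29.73 to 36.43 and 37.89 to 50.36. For DHX58 and PARP9 the C1 and C2 libraries overlapped. For each of these genes every T2 library was below every T1 library. The interferon-stimulated list was called in this comparison (camera adjusted p = 9.87e-13, adjusted p = 0.287 with an estimated correlation). With the replicate block over all 12 libraries edgeR called 0 genes, with 1494 at an unadjusted p under 0.05; without the block DESeq2 called 228 and limma voom 23. None of the 10 named genes kept its call in all 12 fits that left out a library. The count was 0, 5 and 3 without C1 replicates 1, 2 and 3, 4, 9 and 0 without T1 replicates 1, 2 and 3, 41, 3 and 5 without T2 replicates 1, 2 and 3, and 372 and 84 without C2 replicates 1 and 2. The fits without C1 replicate 1 and without T1 replicate 3, with 0 calls by edgeR, had 1122 and 1006 genes at an unadjusted p under 0.05; no other tool was run on them.

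**Figure D4:**
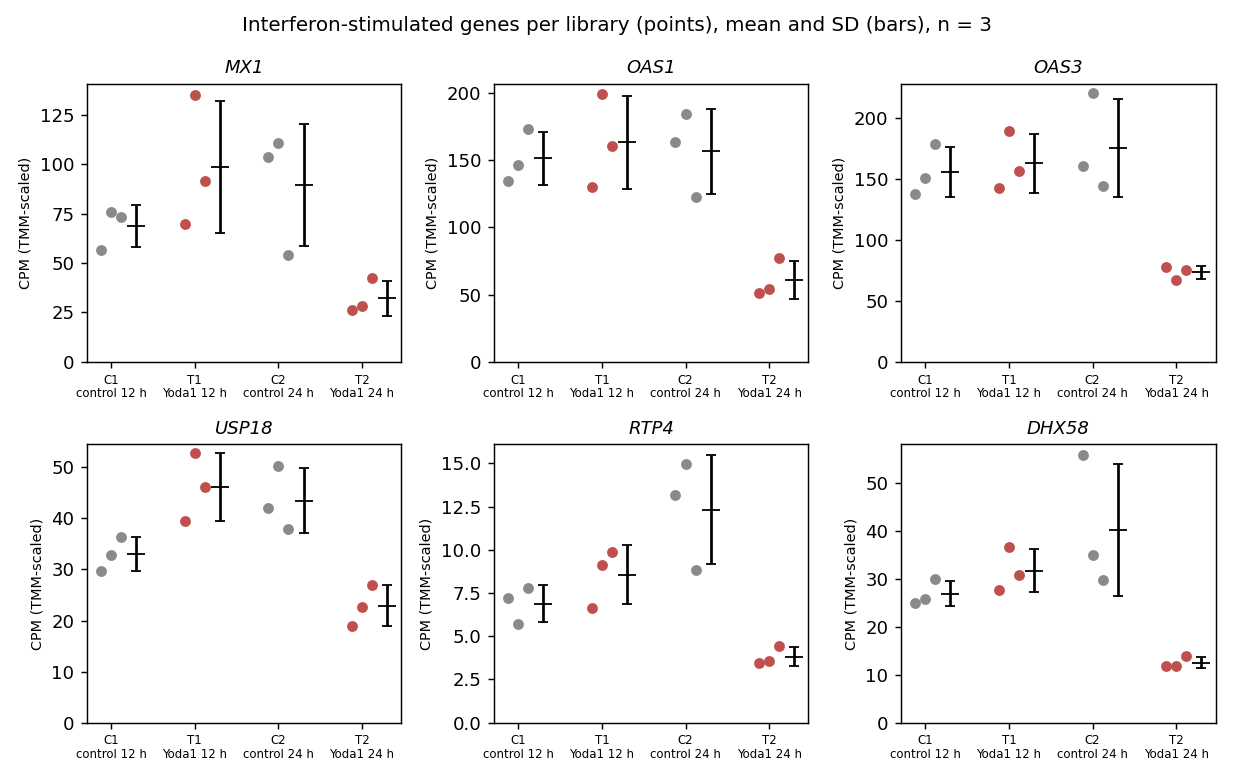
Levels of 6 interferon-responsive genes in TMM-scaled CPM (vertical axes, from 0) in each library; points are libraries, and bars to their right give mean and SD of 3. OAS3 averaged 155 CPM in C1, 162 CPM in T1, 175 CPM in C2 and 73.3 CPM in T2.

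The control groups were compared to show how far they differed without Yoda1. VIM, the intermediate filament vimentin, was lower in C2 (1180 ± 31.9 CPM) than in C1 (2010 ± 53.7 CPM; edgeR adjusted p = 0.017, n = 3 per group). STC1, a secreted glycoprotein, and TMEFF2 were also lower in C2 (-0.81 ± 0.14 and -0.71 ± 0.11), and TEF and ADM, the peptide adrenomedullin, were higher (0.95 ± 0.17 and 0.78 ± 0.12). In all, 23 genes differed, 5 higher and 18 lower in C2, and none of the 5 named genes held its call in every fit that left out a library. The count was 1, 8 and 4 without C1 replicates 1, 2 and 3, 220, 285 and 3 without C2 replicates 1, 2 and 3, 8 and 1 without T1 replicates 1 and 3, and 2 without T2 replicate 2 or T2 replicate 3; with the replicate block it was 3. Of 10 splits of these 6 libraries, another called 160. By camera the G2/M list was higher in C2 (adjusted p = 5.48e-12, adjusted p = 0.283 with an estimated correlation), with 9 of 30 genes higher adjusted over the list alone. Over all genes edgeR called 0 of the 30, with 16 at an unadjusted p under 0.05, 2 called by DESeq2 and 0 by limma voom. The S phase list was higher as well (camera adjusted p = 7.14e-06, adjusted p = 0.492 with an estimated correlation). Of its 26 genes edgeR called 0, with 9 at an unadjusted p under 0.05, 1 called by DESeq2 and 0 by limma voom, and 1 was higher adjusted over the list alone. The epithelial-mesenchymal transition list, to which VIM belongs, was lower (adjusted p = 9.41e-06, adjusted p = 0.283 with an estimated correlation), with 1 of 18 genes lower (adjusted over the list alone, 2). In all, camera called 11 of 31 lists between the controls, 5 higher and 6 lower in C2, and 0 with an estimated correlation, where the smallest adjusted p was 0.208. The 6 lower lists were integrin and focal adhesion, extracellular matrix, calcium, epithelial-mesenchymal transition, WNT and Notch, and ribosomal proteins. These 6 and the 2 cell cycle lists were called in the same direction at 12 h, in a comparison that shares the C1 libraries. Independent calls would give 2.71 lower and 0.323 higher lists. In 100 simulations of unchanged counts the median was 0 and the highest 1, without the correlation among genes that the libraries may hold. With no group difference simulated, few lists could be called at all, so these counts cannot show how many shared calls the C1 libraries would give. Medians had the same sign in 17 of 31 lists, against a median of 20 in the simulations. Part of the shared calls may come from the shared controls.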

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

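Of the tests given here, those of gene length and of the control groups behind the interferon list were chosen only after the result was seen. No outlier test was run, since all groups held 3 libraries.

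In the fit without the replicate block the response differed between 24 h and 12 h, by edgeR's test of the difference itself, for named genes with these log2 differences: GDPD2 1.34, MALL 1.34, TMEFF2 0.97, PINX1 0.85, PLA2G4A 0.77, SESN2 -0.85, NR1D2 -1.29, OAS3 -1.32, USP18 -1.41, PARP9 -1.48, TEF -1.81, DHX58 -1.92 and RTP4 -2.00. By camera it differed for lists with these median log2 differences: tight junction -0.143, extracellular matrix 0.284, epithelial-mesenchymal transition 0.26, G2/M -0.135, NF-kB 0.232, interferon-stimulated -0.458, epithelial and renal tubule identity -0.18 and ribosomal proteins 0.103. None of these lists was called with an estimated correlation, where the smallest adjusted p of the comparison was 0.287. Of 100 drawn splits of the 200 that exchange the times within control and within treated libraries, 2 gave as many genes as the real 22, the real one included. The highest other gave 32. Neither this fit nor the exchange keeps the assumed pairs of C1 and T1 libraries. With the replicate block edgeR called 0 genes, with 1494 at an unadjusted p under 0.05. Without the block DESeq2 called 228 and limma voom 23. The block gives each replicate number 1 effect in all groups, but between C1 and C2 the numbers correlated at -0.00831, -0.19 and -0.205. The 0 calls with the block thus do not decide the question. With the block and length correction edgeR called 20, 13 of them among the 22, so whether chance can be excluded stays open.

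The interferon-stimulated genes formed the first pattern: their median log2 fold change was 0.07 at 12 h and -0.89 at 24 h, where 15 of 15 members lay below 0. By camera at the preset correlation of 0.01, the tables argue against a single library as the cause of the call. The list's adjusted p in the comparison of times was at most 1.83e-05 in the 12 fits that left out a library. The members' estimated correlation was 0.334, with which these fits were not run, so their p may be too small. The tables also argue against a rise in the 24 h controls alone. The members' median was -0.29 from T1 to T2, with 14 of 15 below 0, while it was 0.17 from C1 to C2. A later effect of Yoda1 may account for it, as a hypothesis. A difference in culture between the times was not tested and stays open, as does correlation among the members, with which the list was not called (adjusted p = 0.287). By fry the list was not called in the comparison of times either (adjusted p = 0.127), though it was at 24 h (adjusted p = 0.00755).

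The lower adherens junction, tight junction, desmosome and integrin lists at 12 h formed the second pattern. The tables argue against low counts as the cause: of 10000 random sets matched on mean CPM, 0 had a median as low as the -0.193 of the 64 member genes. Removing the trend with gene length, by camera on log2 CPM with and without the replicate block, left the adherens junction and integrin lists at an adjusted p of at most 0.0134, which argues against length bias there. For the tight junction and desmosome lists that correction lowered the adjusted p in the same test, from 0.0617 and 0.0642 to 0.0457 and 0.0349, and with the block from 0.109 and 0.097 to 0.0761 and 0.0709. Their mean over other genes went from -0.22 and -0.23 to -0.228 and -0.263, so it did not shrink as length bias would need. Neither list passed that test with the block, but neither did so there before the correction, so that failure does not bear on length. By the rule set for the test, which asked for calls in both fits, no decision was reached. The median went from -0.129 to -0.132 for tight junction and from -0.159 to -0.132 for desmosome genes. The values argue against length bias as the source of the shift in these 2 lists, while whether the lists were lower with the block stays open. Correlation among members stays open for all 4 lists, none of which was called with an estimated correlation. By fry the tight junction, desmosome and integrin lists were just under the threshold (adjusted p = 0.0482, 0.0482 and 0.0484). The adherens junction list was not called by fry (adjusted p = 0.0629). High values in C1 alone also stay open for the integrin list. It was lower in C2 than in C1 (camera adjusted p = 0.0154, adjusted p = 0.529 with an estimated correlation, median -0.093). The adherens junction and desmosome lists were not called between the controls (camera adjusted p = 0.407 and 0.27), nor was the tight junction list (camera adjusted p = 0.0541, upward).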

How the results depend on the processing

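The length correction, its combination with the replicate block, camera on log2 CPM, the block in 6 libraries, and some settings of the overlap (limma voom, 6 libraries, pooled controls, TPM) were chosen after the data had been seen. No gene of the naming rule changed sign under a setting run for it; MOB3B, the clock genes DBP, CRY2 and BHLHE41, and the differences between times of SESN2, NR1D2 and OAS3 were not followed under the alternatives. Of the named genes, 27 of 67 at 12 h, 69 of 111 at 24 h, 0 of 10 for the difference between times and 0 of 5 for C2 against C1 held their call in every fit that left out a library. The cause of the changes below was not tested. Leaving out a library or fitting 6 leaves fewer samples, though some counts rose in such fits.

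The 990 genes at 12 h became 1646 with DESeq2, 1673 with only the 6 libraries, 4339 with the replicate block in those 6, 1549 with pooled controls and 145 with a log2 fold change of at least 1, and ranged from 185 to 1695 when a library was left out. In counts simulated without pairs DESeq2 gave 146 true and 28 false calls. The blocked fit of 6 libraries, with 2 residual degrees of freedom, gave 116 true and 19 false calls there. In the data that blocked fit ended the call of 2 of the 67 named genes, MMP9 and CCND1, and of 1 list. The 2630 genes at 24 h became 1080 with only the 6 libraries and 373 with a log2 fold change of at least 1, and ranged from 1138 to 3332. The 22 genes of the difference between times became 228 with DESeq2, 34 without a filter, 47 with a mean of at least 5 CPM, 0 with the replicate block, 20 with the block and length correction, 12 with log2(TPM + 1) and 54 with length correction alone, and ranged from 0 to 372. The 23 genes between C2 and C1 became 258 with DESeq2, 3 with the replicate block, 5 with log2(TPM + 1) and 8 with the replicate block and length correction, and ranged from 1 to 285. The overlap of 629 became 986 with DESeq2 and 1159 with pooled controls, where the comparisons share controls, and ranged from 130 to 1043. The replicate block over all 12 libraries gave 982 genes at 12 h, 2634 at 24 h and 629 shared, with 16 and 5 lists. Between C2 and T2 the replicate numbers correlated at 0.0631, -0.0767 and -0.0841 and not each best with its own, so there they are only numbers.

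The 16 lists at 12 h became 0 with an estimated correlation, 10 with fry and 13 by camera on log2 CPM, and ranged from 13 to 17; the 4 at 24 h became 0 with an estimated correlation, 11 with fry and 18 with pooled controls, and ranged from 4 to 16. With an estimated correlation 4 and 4 lists had an unadjusted p under 0.05. The ribosomal list's median at 12 h ranged from -0.162 without T1 replicate 2 to 0.008 without C1 replicate 2, where its direction reversed.

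With 10 splits of 3 against 3 libraries no share under 0.05 can be reached. The real split called 990 genes at 12 h and the highest other 0; at 24 h these were 2630 and 0, between C2 and C1 23 and 160, so that another division of the controls, a structure of those samples, gave more genes. For lists the values were 16 and 11 at 12 h, and 4 and 16 at 24 h, where the real split gave the fewest of the 10. In the paired fit at 12 h, 4 exchanges within pairs gave 4339 and at most 0. For the 629 shared calls 200 splits at both times decide nothing: none of the 99 other divisions called genes at both times, so their overlap was fixed at 0, and the highest other, 5, was the real division with 1 time mirrored.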

Other observations

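The clock list and its test were chosen after TEF and NR1D2 had been seen, and before the values of the other clock genes were.

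In the primary cilium list 3 of 19 genes fell at 24 h (adjusted over the list alone, 3; camera adjusted p = 0.295), with the ciliary genes TTC8 at -0.84 ± 0.16 and TMEM67 at -0.75 ± 0.15. The histone gene H2AC6 fell at 24 h (-1.47 ± 0.28), in a list where 1 of 6 genes rose and 3 fell (adjusted over the list alone, 1 and 3, camera adjusted p = 0.217). H2AC6 was 1.633 to 2.223 CPM in C1, 1.956 to 4.62 in C2, 1.189 to 1.486 in T1 and 1.134 to 1.374 in T2. By camera the list was higher in C2 than in C1 (adjusted p = 0.0025, adjusted p = 0.208 with an estimated correlation), so part of the fall may lie in the controls. CORO1A, an actin regulator, rose at 24 h (1.36 ± 0.30) from a low 0.47 CPM in C2, as the 1 called of 4 tested leukocyte markers (adjusted over the list alone, 1), while the other 3 had values below 0. Of 4 endothelial markers 2 fell at 24 h (adjusted over the list alone, 3), among them TIE1 (-1.72 ± 0.31), which also fell at 12 h (-2.03 ± 0.35), from a low 1.07 CPM in C2 and 0.658 CPM in C1. The 3 tested fibroblast markers lay below 0 at 12 h (median -0.886, none called by edgeR; adjusted over the list alone, 1 fell), and 2 of them above 0 at 24 h (median 0.008).

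In the fit without the replicate block TEF and NR1D2, transcription factors of the circadian clock, differed in response between times. With the block over all 12 libraries edgeR called 0 genes for this difference, with 1494 at an unadjusted p under 0.05. That block gives each replicate number 1 effect in all groups, though the numbers did not pair at 24 h, so its 0 calls do not decide. A hypothesis is that clock gene expression was shifted between the groups. The 14 other tested genes of a clock list had a median difference of -0.17 between 24 h and 12 h (camera p = 0.0245, 0.0438 with an estimated correlation), and a median of 0.2 from C1 to C2 (camera p = 0.0248), a comparison of control libraries that also enter the first, and none of the 14 was called by edgeR for the difference. The list's camera p was 0.0713 at 12 h (median 0.14) and 0.727 at 24 h (median -0.03). Of its members DBP (-1.10) and CRY2 (-0.68) fell and BHLHE41 rose (0.41) at 24 h, named after their values were seen. The test asks whether members move in a common direction, so it cannot decide on a shift that moves them in opposite directions. Its p-values were not adjusted over the comparisons. Lists were also called in other splits of these samples, up to 16 at 24 h, so the p may be too small. The values leave a shift open, and a difference in the hour of harvest was not tested.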
